A study of Mus musculus with 3 samples.

How the data were processed

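The 3 libraries analysed here are miCLIP libraries (iCLIP with an antibody against m6A) from wild-type mouse v6.5 embryonic stem cells in 2iLIF, replicates 1, 2 and 3 of 1 group. Per the submitters' processing notes, reads were aligned with STAR to GRCm38.p5. The STAR version, the handling of PCR duplicates and of reads that map to several places, and the rule that sets the crosslink base are not given in the sources used here. Each file as deposited is a table of single bases with strand, and its score was taken as a raw count of cDNAs with no normalization by the authors. This unit was read from the values, which are whole numbers of at least 1, and the labels do not say whether the count is of cDNAs or of reads. With no control, input or knockout library, no comparison between groups of samples was possible, and comparisons were made between 2 classes of positions within the same libraries.

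Positions were placed on GENCODE vM21 (GRCm38). Each protein-coding gene had 1 representative transcript, the one with the longest CDS and then the longest transcript among those with a complete CDS, which gave 21478 transcripts. Of 21537 genes, 59 had no sequence and were left out. Of the used genes, 251 share exonic bases with another. Regions were assigned in the order CDS, 3' UTR, 5' UTR, noncoding exon and intron. Copies of snRNAs were classed by RefSeq products. Depth was 389468 to 465329 counts per library, of which 215811 to 257761 lay on the representative mRNAs.

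In each of 5 comparisons, counts of the 2 classes in the 3 libraries were tested with edgeR 4.0.16 (quasi-likelihood fit and test, two-sided) in R 4.3.3 with limma 3.58.1. The offset was the log of library total times number of positions, the library was a block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Near-stop positions were those within 200 nt of the stop codon, against the rest of the spliced mRNA, with at least 30 counts per gene and 100 positions per class. DRACH positions were those within 2 nt of the A, against the rest of the mRNA, with at least 30 counts and 20 positions per class, and the reversed motif HCARD was run as a control. Single DRACH sites were compared with the rest of 50 nt on either side, with at least 15 counts. The first 50 nt were compared with the rest of 5' UTRs of at least 100 nt, with at least 15 counts. CDS positions 100 nt or more from every exon-exon junction were compared with nearer ones, without the 200 nt on either side of the stop codon, with at least 30 counts and 100 positions per class. Where a class had 0 counts, the bound on the fold used a floor of 3 counts summed over the 3 libraries. Where it had 1 to 3, a 95% counting interval was given.

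On simulated data with 100 features changed 2-fold and 100 changed 4-fold, the test recovered 10% and 74% for the near-stop comparison (5526 genes) and 21% and 74% for DRACH per gene (5527 genes). It recovered 24% and 70% for junctions (1870 genes) and 10% and 44% for the 5' end (687 genes). For single sites (23269) it recovered 0% and 0%. Of the unchanged features, 2, 1, 4, 0 and 0 were called in these 5 comparisons.

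Gene lists were naive pluripotency, core pluripotency, formative and primed state, epithelial polarity and lumen, m6A writers, erasers and readers, chromatin regulators, immediate early and signalling feedback genes, cytosolic ribosomal proteins, replication-dependent histones, the nuclear-encoded respiratory chain, proteasome subunits, glycolysis, C2H2 zinc finger genes, and markers of fibroblasts, primitive endoderm, trophectoderm and 2-cell-like cells. List medians were compared with 10000 random lists of the same size matched on deciles of mean count, a two-sided permutation test, adjusted over 26 list tests. On simulated data, 9 of 100 unchanged lists of 20 genes had an unadjusted p under 0.05, and 72 of 100 lists shifted by 1 on the log2 scale.

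Genes were named by a rule. For the near-stop and DRACH comparisons it took genes past the threshold with the same sign in 3 libraries and a mean of at least 50 counts per library. Of these it named the 8 highest and 8 lowest, and from each list up to 2 tested members with the most counts. For sites with at least 5 counts in every library, it named the 8 with the highest ratio and the 8 with the most counts. For the 5' end and junctions it named the 4 highest and 4 lowest with a mean of at least 20 counts. A few genes that the rule named are not reported here. Mat2a, Malat1, Neat1, Xist, U6, U2 and the mitochondrial mRNAs were named in advance. The comparisons, lists, naming rule and main alternatives were chosen before the data were examined.

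Alternatives were DESeq2 1.42.0 (Wald test), TMM factors between the classes, no count minimum or a minimum 3 times as high, each position counted once, no replicate block, leaving out each library, other windows and flanks, lists matched on 3' UTR length, and regions without the mitochondrial genome or with noncoding exons first. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the other steps.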

Results

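Crosslink positions of an antibody against N6-methyladenosine (m6A), the most common internal methylation of mRNA, were mapped in mouse embryonic stem cells by iCLIP, which places each cDNA end beside the crosslinked base. The cells were wild type, of the v6.5 line, and kept in the naive state in 2iLIF, a medium with inhibitors of MEK and GSK3 and with the cytokine LIF. All 3 libraries formed 1 group, replicates 1, 2 and 3. No control, input or knockout library was analysed here, so every comparison was between classes of positions within the same libraries. The series title ties the libraries to LIN28A, mRNA decay and formation of the embryonic lumen. The labels give m6A mapping in stem cells as the purpose of these libraries. Replicates 1, 2 and 3 held 440857, 389468 and 465329 cDNAs at 338547, 304113 and 368144 positions. The values were taken as cDNA counts, which the labels do not state. A single cDNA was present at 89.2%, 88.6% and 91.2% of these positions. Nothing in the labels says that the replicates came from separate cultures, so edgeR p-values covered only counting error and the spread between these samples, which may be technical. That spread was estimated with pooling over features. Near the stop codon and for sites the pooling was complete, with infinite prior degrees of freedom. Permutation p-values measured the spread between random gene lists, and Fisher's exact p-values compared counts of sites or genes. Neither used the spread between libraries. Intervals and bounds covered counting error only.

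The libraries ranked genes alike but differed by more than the noise of independent counts, which reads copied in PCR would also exceed. Over 6295 genes, chi-square divided by its degrees of freedom was 1.31 for replicates 1 and 2 (p = 3.88e-56). The chi-square ratio was 1.29 for replicates 1 and 3 (p = 1.21e-50) and 1.14 for replicates 2 and 3 (p = 3.05e-14). Across genes, which are not independent replicates, Pearson correlations of log2 counts were 0.915 to 0.923 and Spearman correlations were 0.873 to 0.882. Of the positions of 2 libraries, 9.76% ± 0.884 (SD, n = 3 pairs) fell on the same base, against 3.33% ± 0.252 after a shift of 50 nt. Within 5 nt, the shared percentage was 28.8 ± 1.67, against 16.1 ± 1.10 after the shift.

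Coding exons held the largest part of the cDNAs. CDS positions took 32.8% ± 0.617 (SD, n = 3), 3' UTRs 20.02% ± 0.0979, noncoding RNA exons 14.5% ± 0.538, introns 14.0% ± 0.444 and 5' UTRs 5.08% ± 0.108. Intergenic positions took 8.36% ± 0.269, positions antisense to genes 3.84% ± 0.191 and other exons of coding genes 1.39% ± 0.0406. Per kb of annotated region and per 1000000 cDNAs, the density was 9.05 ± 0.170 in CDS, 7.18 ± 0.153 in 5' UTRs, 6.15 ± 0.0301 in 3' UTRs and 4.31 ± 0.160 in noncoding RNA exons. Intron density was 0.123 ± 0.00388. With each position counted once per library, the share of noncoding RNA exons was 4.64%. These shares had no test, since a sign flip test on 3 libraries cannot go below 0.25.

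Stable noncoding RNAs carried many cDNAs at few positions. Per 1000000 cDNAs, the mitochondrial rRNA mt-Rnr2 had 35782 ± 798 (SD, n = 3), mt-Rnr1 had 25421 ± 571 and the nuclear lincRNA Malat1 had 2842 ± 118. The 13 mitochondrial mRNAs together had 6782 ± 473. Mat2a, which encodes a methionine adenosyltransferase and is a known METTL16 target, had 206 ± 20.9, and the paraspeckle RNA Neat1 had 205 ± 55.4. Xist, the RNA that silences an X chromosome, had 0 cDNAs in the 3 libraries, which allows up to 3 over all of them. Copies of the spliceosomal U6 snRNA took 1.52% ± 0.145 of cDNAs and U2 copies took 0.809% ± 0.0560. On full-length U6 copies, position 40 from the 5' end held 32.9% ± 3.88 of the cDNAs, position 30 held 11.1% ± 0.923 and position 43 held 6.23% ± 0.532. At position 40, 1 locus held 1416, 1356 and 1672 of the 1642, 1514 and 1885 cDNAs in replicates 1, 2 and 3. At position 30, another locus held 663, 426 and 521 of 703, 456 and 567. Positions 40 and 30 were therefore not shown to be shared between U6 copies. On U2 copies, position 54 held 24.2% ± 1.42. Whether reads from rRNAs, snRNAs or other repeated RNAs were set aside before these positions were made is not given in the sources used here, so the shares of these RNAs hold for the files as deposited only. The copies of each snRNA are near-identical, so the split of cDNAs between their loci is uncertain.

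Sequence around the crosslinks was compared next, since the METTL3 and METTL14 methyltransferase acts at the consensus DRACH (D for A, G or T, R for A or G, H for A, C or T). In mature mRNAs, cDNA density 1 base before the A of DRACH was 4.29 ± 0.197 times the mRNA mean (SD, n = 3). At the reversed motif HCARD, of the same base composition, it was 0.906 ± 0.0330 there and peaked at 1.70 ± 0.0518 at 3 bases before the A. Where the first bases of HCARD are the A and C of an overlapping DRACH, that is the base before the DRACH A. How much of the HCARD peak came from such overlaps was not measured. For GGACT, density 1 base before the A reached 11.2 ± 0.728. Over the 5 positions within 2 nt of the A, GGACT had 4.08 ± 0.141 times the mean density, GAACT 3.58 ± 0.130, AGACT 3.15 ± 0.147, TGACT 2.43 ± 0.0910 and GGACA 2.36 ± 0.0564. TGACC, at 0.852 ± 0.0110, was the lowest of the 18 variants. These folds are over the mean of all mRNA positions, so they include the density of the surrounding sequence. Around GGACT, density was 2.30 ± 0.150 at 20 bases before the A and 1.46 ± 0.145 at 20 bases after it. Within 2 nt of that A, positions other than the base before it were at 1.07 to 3.03. Flanks of the other variants were not measured. Crosslinked bases were T in 32.2% ± 0.241 of mRNA cDNAs, against 25.3% of mRNA positions. By region, the share of positions 1 base before a DRACH A was 3.54 ± 0.133 times that of positions moved 30 nt in 3' UTRs, 3.27 ± 0.124 in CDS and 2.65 ± 0.190 in 5' UTRs. In the mitochondrial genome it was 1.11 ± 0.0674 times.

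**Figure D1:**
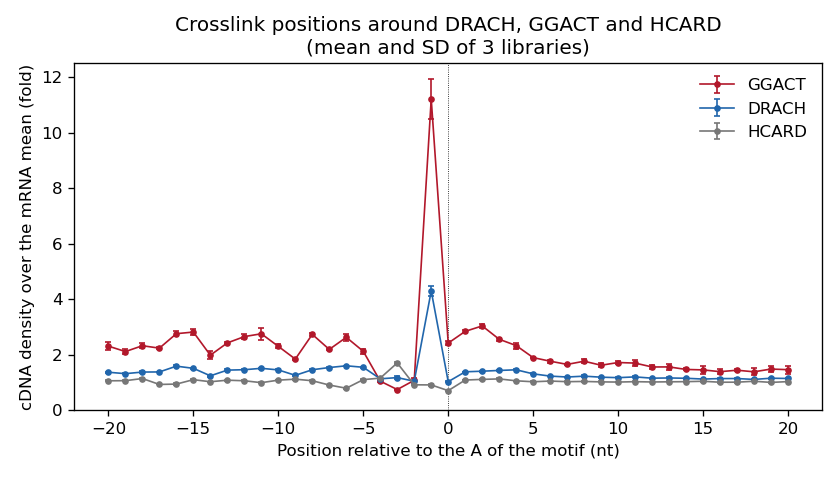
cDNA density (y axis, fold over the mean of mature mRNA positions) at each position relative to the A of the motif (x axis, nt), as mean and SD of 3 libraries, for GGACT, DRACH and HCARD. GGACT and DRACH peak 1 base before the A, at 11.2 and 4.29, where HCARD is at 0.906. HCARD peaks 3 bases before the A at 1.70, which is the base before the A of a DRACH that overlaps its start.

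The DRACH comparison within genes asked whether crosslinks lie at the consensus more than elsewhere in the same mRNA. Density within 2 nt of a DRACH A was higher than in the rest of the mRNA in 2360 of 5527 tested genes (42.7%) and lower in 31, with a median ratio of 1.99. Pcbp1, a poly(C)-binding protein, Zfp36l2, which binds AU-rich elements and promotes mRNA decay, Suz12, a subunit of the Polycomb repressive complex, and Klf2, a naive pluripotency factor, had among the highest ratios. Several replication-dependent histone mRNAs and Mt1, a metallothionein, were lower at DRACH. The library medians of the log2 ratio averaged 1.09 ± 0.03 (SD, n = 3).

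Log2 ratios at DRACH were 2.58 for Pcbp1 (SE 0.13, edgeR adjusted p = 2.12e-47), 2.48 for Zfp36l2 (SE 0.26, adjusted p = 5.85e-16) and 2.43 for Suz12 (SE 0.17, adjusted p = 1.15e-28). They were 2.40 for Slc25a3, the mitochondrial phosphate carrier, 2.38 for Klf2, 2.23 for the AP-1 factor Jund and 2.14 for the transcriptional repressor Zbtb7a. All of these were higher in 3 of 3 libraries and stayed so with TMM scaling, where the log2 ratio of Pcbp1 was 1.56. Of the 51 cDNAs of Slc25a3 at DRACH, 29 lay at 1 site in the 5' UTR close to the annotated start. Only 3 of these 29 were on the base before the A, and whether they belong to the DRACH or to the 5' end was not tested. At the other end, Hist1h2bc and Hist1h2bg had 0 cDNAs at DRACH and 212 and 181 elsewhere, at least 5.89-fold and 3.62-fold lower against a floor of 3 counts over the libraries. Hist1h3f had 3 cDNAs at DRACH, a log2 ratio of -3.93 with a 95% counting interval of -6.24 to -2.40. Snrpd3, a core Sm protein of the spliceosome, was at -2.13 (edgeR adjusted p = 0.000390), Mt1 at -1.80 (adjusted p = 2.07e-07), Hist1h3b at -1.71, Hist1h3c at -1.54 and Hist1h4a at -1.38. With each position counted once per library, Hist1h3b, Hist1h3c and Hist1h4a turned to 0.07, 0.75 and 0.40. Histone genes are near-identical copies, so their counts are uncertain.

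Of 16 naive pluripotency genes, 12 were higher at DRACH and 0 lower, both over all genes and adjusted over the list alone, among them Klf2 and Klf5 (1.09, SE 0.17). Tfcp2l1, Prdm14, Dppa3 and Stat3 did not pass the test. Of 13 core pluripotency genes, 10 were higher (11 adjusted over the list alone), among them Sox2 at 0.81 (-0.20 with TMM scaling) and the translational repressor Trim71 at 1.02. Dppa2, Dppa4 and Tdgf1 did not pass. Of 7 formative and primed genes, 4 were higher (5 adjusted over the list alone): Sox4, Lef1, Foxd3 and Zic2, at 1.42. Dnmt3a, Dnmt3b and Sox11, at 0.56 (SE 0.43), did not pass. Of 11 epithelial polarity and lumen genes, 6 were higher (6 adjusted over the list alone), among them E-cadherin (Cdh1, 1.19) and the laminin chain Lamc1 (0.62, and -0.39 with TMM scaling), and Pard3, Prkci, Itgb1, Epcam and Mpp5 did not pass. Of 19 m6A writers, erasers and readers, 12 were higher (14 adjusted over the list alone), among them the writer subunit Rbm15 at 1.44, and Hnrnpa2b1 was at -0.04 without a call. Of 25 chromatin regulators, 16 were higher (16 adjusted over the list alone), among them Arid1a at 1.497 and Kmt2d at 1.35. None of these 6 lists had a lower gene by edgeR, with 0 also at an unadjusted p under 0.05 and 0 by DESeq2. Genes named for a small count were chosen after their values were seen.

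Immediate early and signalling feedback genes stood above random lists. Of 14 tested, 11 were higher at DRACH and 0 lower (11 and 0 adjusted over the list alone), among them Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, at 1.80, and Mycn at 1.73. Their median log2 ratio was 1.64, against 1.02 for random lists matched on mean count (adjusted permutation p = 0.00104 over 26 list tests, from p = 0.0002, the smallest that 10000 random lists can give). Replication-dependent histones lay below random lists, with a median of -0.78 over 24 genes, or -0.53 with 5 genes at their bounds, 5 higher and 8 lower (5 and 8 adjusted over the list alone; adjusted permutation p = 0.00104). The 5 higher were Hist1h1d, Hist1h2ad, Hist1h4b, Hist1h2bm and Hist1h4d. Housekeeping lists also lay below random lists. The respiratory chain had a median of 0.39 (-0.62 with TMM scaling) over 43 genes, with 5 higher and 2 lower (3 and 1 adjusted over the list alone; adjusted permutation p = 0.00173). Atp5l, Ndufa2, Atp5j2, Sdhd and Ndufa13 were the 5 higher, and Uqcrc2 and Atp5g3 the 2 lower, while DESeq2 called 4 higher and 0 lower. In Atp5l, 1 site close to the annotated start of the mRNA held 29 cDNAs, with 2 on the base before the A. Proteasome subunits had a median of 0.37 (-0.63 with TMM scaling) over 27 genes, with Psmd7 (1.70), Psmd5 and Psmb7 higher and Psmb4 (-1.33) lower (1 and 0 adjusted over the list alone; 3 and 0 by DESeq2; adjusted permutation p = 0.00195). Cytosolic ribosomal proteins had a median of 0.54 (-0.45 with TMM scaling) over 49 genes, with 6 higher, among them Rpl4 at 0.86 and Rps3 at 0.76 (-0.15 and -0.25 with TMM scaling), and 0 lower (3 and 0 adjusted over the list alone; adjusted permutation p = 0.00404). Glycolysis genes had a median of 0.42 (-0.58 with TMM scaling) over 12 genes, with Hk2 (0.69, and -0.32 with TMM scaling), Pfkl and Pkm (1.15) higher and 0 lower (3 and 0 adjusted over the list alone; adjusted permutation p = 0.0208). The counts of 0 lower for immediate early, ribosomal protein and glycolysis genes came from edgeR and were 0 also at an unadjusted p under 0.05 and by DESeq2. Matched on 3' UTR length instead, the adjusted permutation p was 0.0745 for ribosomal proteins and 0.0945 for glycolysis.

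The other lists did not differ from random lists at DRACH. Their medians were 1.27 for naive pluripotency (adjusted permutation p = 0.219), 1.17 for core pluripotency (p = 0.581), 1.36 for formative and primed genes (p = 0.294) and 0.87 for epithelial polarity and lumen genes (p = 0.527; median -0.14 with TMM scaling). They were 1.11 for m6A writers, erasers and readers (adjusted permutation p = 0.696), 0.99 for chromatin regulators (p = 0.546; median -0.01 with TMM scaling) and 1.12 for 182 C2H2 zinc finger genes (p = 0.0643). Of the zinc finger genes, 93 were higher and edgeR called 0 lower (97 and 0 adjusted over the list alone; 110 and 0 at an unadjusted p under 0.05, and 80 and 0 by DESeq2), among them Zfp292 at 0.74 and Zfp106 at 0.996 (-0.27 and -0.02 with TMM scaling). Atp5b at -0.05 and Atp5a1 at 0.25, subunits of ATP synthase, had no call. Among markers of other cell types, the trophectoderm genes Cdx2 (1.53, SE 0.75) and Eomes (1.40, SE 0.66) and the primitive endoderm gene Lama1 (0.81, SE 0.80) were tested, without a call. The fibroblast and 2-cell-like lists had 0 cDNAs and no tested gene.

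The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the library as a block. The control motif HCARD gave 31 genes higher and 45 lower of 5530, with a median log2 ratio of -0.12. TMM scaling, which centres the ratios on the typical gene, moved the median by -1.005 and gave 101 genes higher and 117 lower. Without replicate 1 there were 1092 genes higher and 9 lower, and without replicate 3 there were 833 and 7. Without replicate 2 edgeR called 0, with 2007 higher and 22 lower at an unadjusted p under 0.05 and a median log2 ratio of 1.00. On the A and the next base alone, 32 genes were higher and 4 lower.

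**Figure D2:**
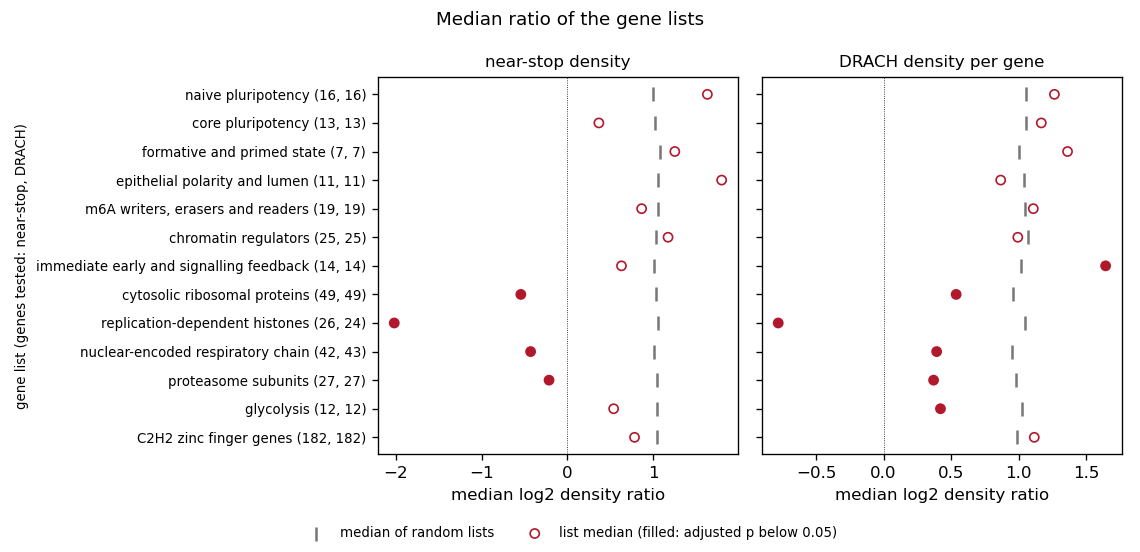
Median log2 density ratio (x axis) of each gene list (y axis, with the number of genes tested) near the stop codon (left) and at DRACH (right), with grey bars for the medians of 10000 random lists matched on mean count and filled circles for an adjusted permutation p under 0.05. TMM scaling moves below 0 the core pluripotency, m6A, immediate early, glycolysis and C2H2 zinc finger medians at left and the epithelial polarity, chromatin, ribosomal protein, respiratory chain, proteasome and glycolysis medians at right.

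The near-stop comparison asked whether crosslink density within 200 nt of the stop codon differs from the rest of the same mRNA. It was higher near the stop codon in 2695 of 5526 genes (48.8%) and lower in 351 (6.35%), with a median ratio of 2.06. Serbp1, an mRNA-binding protein found with ribosomes, Ctbp2, a transcriptional corepressor, Hspg2, the basement membrane proteoglycan perlecan, and Tomm70a, a mitochondrial import receptor, had among the highest ratios. Mybl2, a transcription factor of cell cycle genes, Pcna, the sliding clamp of DNA replication, and 17 of 26 tested replication-dependent histone genes were lower near the stop codon, while 4 were higher and 5 not called. A profile was taken over the 7428 mRNAs with at least 1000 nt before and after the stop codon. Its density peaked at 3.00 ± 0.0351 times the mean of all mRNAs (SD, n = 3) in the last 25 nt of the CDS. It was 2.90 ± 0.0643 times at 50 to 74 nt after the stop codon.

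**Figure D3:**
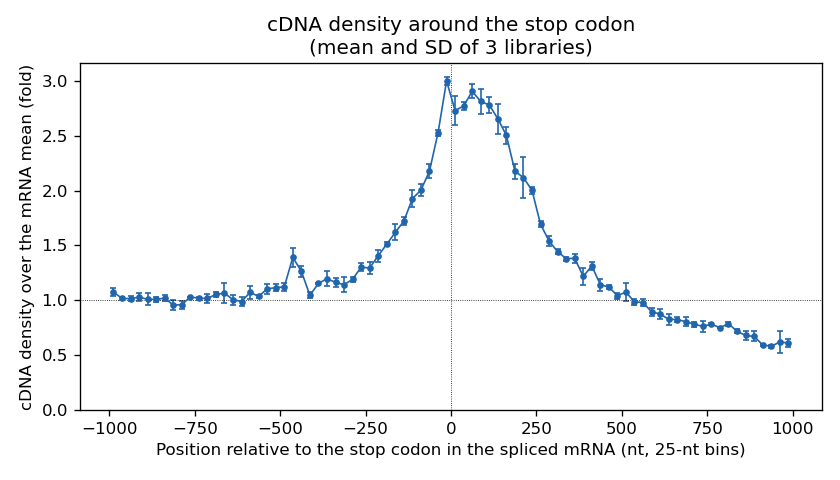
cDNA density (y axis, fold over the mean of mature mRNA positions) in 25-nt bins of the spliced mRNA relative to the stop codon (x axis, nt), as mean and SD of 3 libraries. The density peaks at 3.00 in the last bin of the CDS. Only the 7428 mRNAs with at least 1000 nt before and after the stop codon are included.

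Log2 ratios near the stop codon were 7.70 for D10Wsu102e (SE 0.35, edgeR adjusted p = 9.76e-103), 4.96 for Ctbp2 (SE 0.20, adjusted p = 1.45e-135), 4.46 for Hspg2 (SE 0.29, adjusted p = 6.86e-50) and 4.39 for Tomm70a (SE 0.19, adjusted p = 1.87e-117). Serbp1 was at 5.58 (SE 0.12), with 692 cDNAs near the stop codon and 541 elsewhere. The RNA-binding iron regulator Ireb2 was at 4.11, Mtdh at 4.14 and the bromodomain protein Phip at 4.03. All 8 were higher in 3 of 3 libraries and with TMM scaling. The annotated transcript of D10Wsu102e has 122778 nt outside the window, and that of Serbp1 15073 nt. Against the rest of the CDS alone, D10Wsu102e was at 4.53 and Serbp1 at 2.60. Of the genes lower near the stop codon, Mybl2 had 0 cDNAs near the stop codon and 235 elsewhere, at least 9.67-fold lower. The centriole protein Cep295 was at least 3.61-fold lower, the nuclear protein Rai1 at least 2.91-fold and the basal body protein Alms1 at least 1.97-fold. Pcna had 3 cDNAs near the stop codon and 361 elsewhere, a log2 ratio of -5.34 with a 95% counting interval of -7.72 to -3.87. Hist1h2bg was at -5.24 (SE 0.31, edgeR adjusted p = 1.46e-61) and Hist1h4a at -4.81 (SE 0.17, adjusted p = 1.77e-167), or -1.82 against the rest of the CDS alone. In these short genes the near-stop window takes most of the mRNA, 401 nt against 217 nt in Hist1h2bg and 357 nt against 182 nt in Hist1h4a. In some genes most cDNAs outside the window lay in the 5' UTR past its first 50 nt. These were 276 of 361 in Pcna and 466 of 468 in Hist1h3c. Against the rest of the CDS alone, Pcna was at -4.03, while Hist1h3c went from -3.87 to 3.21.

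Of 16 naive pluripotency genes, 12 were higher and 0 lower (12 and 0 adjusted over the list alone), among them Klf2 at 2.83 and Klf5 at 1.11 (-0.02 with TMM scaling), and Zfp42, Nr0b1, Dppa3 and Stat3 did not pass. Of 11 epithelial polarity and lumen genes, 10 were higher and 0 lower (11 and 0 adjusted over the list alone), among them Cdh1 at 1.56 and Lamc1 at 2.87, and Ezr, at 0.56, did not pass. Core pluripotency genes went both ways, with 6 of 13 higher and 3 lower (6 and 3 adjusted over the list alone). Sox2 was at 2.07 and Trim71 at 1.56, and Pou5f1 (-2.39), Sall4 (-1.28) and Tdgf1 were lower, while Utf1, Lin28a (-0.37), Dppa4 and Tet1 did not pass. Tdgf1, a coreceptor of Nodal, rested on 2 cDNAs near the stop codon. Of 7 formative and primed genes, Dnmt3a, Dnmt3b, Sox4 and Sox11 (2.38) were higher and Zic2 (-2.66) lower (4 and 1 adjusted over the list alone). Against the rest of the CDS alone, Sox11 was at 0.96 without a call (edgeR adjusted p = 0.0527) and Zic2 at -2.97. Of 19 m6A writers, erasers and readers, 11 were higher and Ythdf1 (-0.84) lower (11 and 1 adjusted over the list alone), with Hnrnpa2b1 at 0.75 (-0.38 with TMM scaling) and Rbm15 at -0.05 without a call. Of 25 chromatin regulators, 15 were higher and 0 lower (15 and 0 adjusted over the list alone), among them Arid1a at 0.90 (-0.23 with TMM scaling), with Kmt2d at 0.49 (-0.63) without a call. Of 14 immediate early and signalling feedback genes, 7 were higher, among them Mycn at 1.85, and Spry2 (-0.66) was lower (7 and 1 adjusted over the list alone; 4 and 1 by DESeq2). Of 182 C2H2 zinc finger genes, 74 were higher, among them Zfp292 at 1.96, and 7 lower, among them Zfp106 at -0.77 (71 and 6 adjusted over the list alone; 63 and 3 by DESeq2). Of 2 tested trophectoderm genes, Eomes was higher at 1.56 and Cdx2 was at 1.21 without a call, and Lama1, with 0 of its 31 cDNAs near the stop codon, had no call. The counts of 0 lower for naive pluripotency, epithelial polarity and chromatin genes came from edgeR and were 0 also at an unadjusted p under 0.05 and by DESeq2. Genes named for a small count were again chosen after their values were seen.

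Histone, ribosomal protein, respiratory chain and proteasome lists lay below random lists matched on mean count near the stop codon. Random lists matched on 3' UTR length had lower medians. These were 0.51 for histones, 0.47 for ribosomal proteins, 0.47 for the respiratory chain and 0.48 for proteasome subunits. Against them, the adjusted permutation p was 0.0026, 0.00347 and 0.00936 for the first 3 lists. Transcript length was not matched, and the near-stop window takes a larger part of a short mRNA. Replication-dependent histones had a median log2 ratio of -2.02 over 26 genes, with 4 higher and 17 lower (5 and 19 adjusted over the list alone). Random lists matched on mean count had 1.06 (adjusted permutation p = 0.00104). Hist1h3c was at -3.87, and Hist1h1d, Hist1h4d, Hist1h1e and Hist1h2be were the 4 higher. Cytosolic ribosomal proteins had a median of -0.54 over 49 genes, with 8 higher and 15 lower (8 and 15 adjusted over the list alone; adjusted permutation p = 0.00104). Rpl4 at 1.09 and Rps3 at 1.01 were among the higher, and with TMM scaling they were at -0.04 and -0.11. Respiratory chain genes had a median of -0.43 over 42 genes, with 4 higher and 15 lower (4 and 15 adjusted over the list alone; adjusted permutation p = 0.00104). Uqcrfs1, Uqcrq, Ndufb2 and Sdha were higher, Atp5b was lower at -0.76 and Atp5a1 was at 0.16 (-0.97 with TMM scaling) without a call. Proteasome subunits had a median of -0.21 over 27 genes, with 7 higher, among them Psmd7 at 0.77 (-0.36 with TMM scaling), and 5 lower (6 and 5 adjusted over the list alone; adjusted permutation p = 0.00195, and 0.0945 when matched on 3' UTR length). The 5 lower were Psmb4 at -1.97, Psmc3, Psma6, Psmb7 and Psmc5. Against the rest of the CDS alone, Psmb4 was at -0.85 without a call (edgeR adjusted p = 0.0747). Of 12 glycolysis genes, Hk2 (1.85), Gpi1, Pfkl and Eno1 were higher and Gapdh (-1.65) and Pkm (-0.58) lower (4 and 2 adjusted over the list alone; 4 and 0 by DESeq2). The median of glycolysis genes was 0.54 (-0.58 with TMM scaling; adjusted permutation p = 0.430). Medians were 1.64 for naive pluripotency (p = 0.143), 0.37 for core pluripotency (p = 0.294; median -0.74 with TMM scaling), 1.26 for formative and primed genes (p = 0.753) and 1.80 for epithelial polarity and lumen genes (p = 0.219), all adjusted permutation p-values. Their medians were 0.87 for m6A writers, erasers and readers (adjusted permutation p = 0.696; median -0.26 with TMM scaling) and 1.18 for chromatin regulators (p = 0.651). Immediate early and signalling feedback genes had a median of 0.63 (adjusted permutation p = 0.527; median -0.49 with TMM scaling). C2H2 zinc finger genes had a median of 0.79 (adjusted permutation p = 0.142, and 0.0468 when matched on 3' UTR length; median -0.33 with TMM scaling).

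Calls near the stop codon came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. TMM scaling moved the median by -1.12 and gave 1218 genes higher and 1319 lower. Without replicate 1 there were 1732 genes higher and 118 lower. There were 145 lower without replicate 2 and 179 without replicate 3. Spry2 turned above 0 with windows of 100 nt or 400 nt, and Arid1a, Trim71 and Rps3 turned below 0 and Pkm above 0 with 400 nt of 3' UTR as the window. Hist1h3c turned to 3.21 against the rest of the CDS.

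The junction comparison asked whether density in coding sequence is lower near exon-exon junctions. CDS positions 100 nt or more from every junction were denser than those nearer in 1297 of 1870 genes (69.4%) and less dense in 39, with a median ratio of 3.34. In CDS exons of 400 nt or more, density after a junction went from 0.850 ± 0.0345 times the mRNA mean in the 25 nt next to it to 2.24 ± 0.0956 at 175 to 199 nt (SD, n = 3). Before a junction it was 0.716 ± 0.0244 in the nearest 25 nt and 2.01 ± 0.0791 at 175 to 199 nt. Ptrh2, a mitochondrial peptidyl-tRNA hydrolase, and the zinc finger genes Zfp229 and Thap12 were denser far from junctions, as was Nexmif, and Eef1d, a translation elongation factor subunit, was less dense there.

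**Figure D4:**
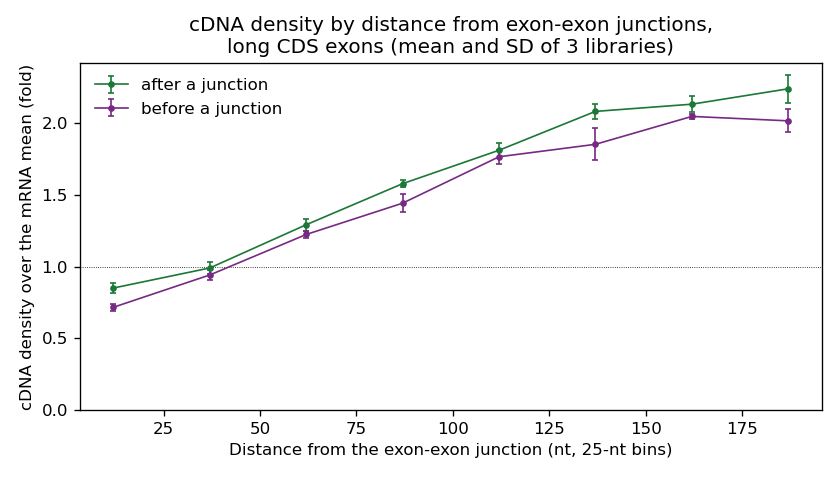
cDNA density (y axis, fold over the mean of mature mRNA positions) by distance from an exon-exon junction (x axis, nt, 25-nt bins) in CDS exons of 400 nt or more, as mean and SD of 3 libraries. Density after a junction goes from 0.850 in the first bin to 2.24 in the last.

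Ptrh2 had 0 cDNAs near junctions and was at least 10.7-fold denser far from them, Zfp229 at least 5.40-fold and Nexmif at least 1.82-fold. Thap12 had 1 cDNA near junctions, a log2 ratio of 5.31 with a 95% counting interval of 3.03 to 10.84. Txnrd1, a thioredoxin reductase, had 0 cDNAs far from junctions and was at least 2.67-fold less dense there, and Bcat1, a branched-chain aminotransferase, at least 2.43-fold. Eef1d was at -3.05 (SE 0.45, edgeR adjusted p = 5.30e-06). Calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the library medians of the log2 ratio averaged 1.67 ± 0.04 (SD, n = 3). TMM scaling moved the median by -1.70 and gave 247 genes higher and 281 lower. Without replicates 1, 2 and 3 there were 20, 15 and 10 genes lower. With 200 nt as the distance, Nexmif and Ptrh2 turned below 0.

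The comparison at the 5' end concerned m6Am, the methylated adenosine beside the cap, which the antibody also binds. The first 50 nt of the mRNA were denser than the rest of the 5' UTR in 118 of 687 genes and less dense in 129, and 100 of the latter had 0 cDNAs in the first 50 nt. Hes1, a transcriptional repressor of the Notch pathway, and the RNA-binding proteins Hnrnpc, Tra2a and Ddx5 were denser in the first 50 nt. The histone genes Hist1h3c, Hist1h3b and Hist1h3f and Pcna were less dense there. Log2 ratios were 6.09 for Hes1 (SE 0.36, edgeR adjusted p = 4.66e-09), 5.63 for Hnrnpc (SE 0.36, adjusted p = 5.46e-09), 4.68 for Tra2a (SE 0.45, adjusted p = 7.04e-07) and 4.26 for Ddx5 (SE 0.32, adjusted p = 6.17e-08). With 0 cDNAs in the first 50 nt, Hist1h3c was at least 141-fold lower, Hist1h3b at least 72.5-fold, Pcna at least 20.2-fold and Hist1h3f at least 18.2-fold. Over the first 20 nt alone, Hnrnpc and Ddx5 turned below 0. TMM scaling gave 58 genes higher and 305 lower. Without replicate 1 or replicate 3, edgeR's quasi-likelihood test called 0 genes, with 84 higher and 48 lower, and 93 and 58, at an unadjusted p under 0.05. Without replicate 2 it called 15 higher and 2 lower.

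Single DRACH sites were compared with the 50 nt on either side. Of 23269 sites in 2838 genes, 444 in 338 genes were denser than their flanks and 27 in 20 genes less dense. The control motif HCARD gave 30 and 12 of 20668. Among the denser sites, 79.5% (95% Clopper-Pearson interval 75.4 to 83.2) ended in T at the last base of the motif, against 40.1% of the other tested sites (odds ratio 5.79, adjusted Fisher's exact p = 3.39e-62). GAACT made up 22.1% against 7.33% (p = 1.62e-21), GGACT 19.6% against 8.83% (p = 1.34e-11) and AGACT 17.6% against 8.30% (p = 1.92e-09), all adjusted Fisher's exact p-values. Sites in 3' UTRs made up 37.8% against 39.5% (p = 0.704), those within 200 nt of the stop codon 30.9% against 31.6% (p = 0.841) and those in 5' UTRs 5.63% against 3.47% (p = 0.0312), from the same exact test. The sites are not independent, since many share a gene and neighbouring ones share flanks, so these p-values may be too small.

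A denser site in the 5' UTR of Ftl1, which encodes the ferritin light chain, was at a GGACT on chromosome 7, position 45459843 (GRCm38). It had 9, 8 and 14 cDNAs in replicates 1, 2 and 3 and 0 in the flanks, at least 180-fold denser (edgeR adjusted p = 6.76e-20), and 0 of these cDNAs lay on the base before the A. Sites in exon 1 of Atp5l, an ATP synthase subunit (chromosome 9, 44920706, log2 ratio 6.66, SE 0.75), and Slc25a3 (chromosome 10, 91123976, 5.05, SE 0.63) lay in 5' UTRs too, with 2 and 3 of 29 cDNAs on that base. The flanks of the Ftl1, Atp5l and Slc25a3 sites held 87, 82 and 73 positions, against 96 for full flanks such as that of Hist1h1d. The annotated start of the mRNA cut them short, so these sites lie close to the 5' end. Whether their cDNAs belong to the DRACH or to the 5' end of the mRNA was not tested. A site in the linker histone gene Hist1h1d (chromosome 13, 23555034) was at 3.46 with 73 cDNAs. Sites in genes of RNA-binding proteins were in the 3' UTRs of Hnrnpdl (3.98) and Hnrnpl (3.56) and the CDS of Pcbp1 (3.51, with 52, 28 and 61 cDNAs). Suz12 had a site in exon 11 (3.93). The base before the A held 15 of 73 cDNAs at the Hist1h1d site, 33 of 141 in Pcbp1 and 10 of 52 in Suz12. It held 9 of 18 in Hnrnpdl and 13 of 20 in Hnrnpl. The sites named for their cDNAs were those of Pcbp1 and Hist1h1d and sites in the beta-tubulin gene Tubb5 (chromosome 17, 35835453, 163 cDNAs, 2.83, and 35835424, 70 cDNAs, 1.45), Klf2 (chromosome 8, 72321009, 81 cDNAs, 1.49), Serbp1 (75 cDNAs, 1.52), Lars2 (63 cDNAs, 1.40) and the elongation factor gene Eef2 (62 cDNAs, 2.80). The 21 nt around the Lars2 site match the genome at 8 places and those of Hnrnpdl, Suz12, Pcbp1, Serbp1 and Eef2 at 2, so these counts are uncertain. TMM scaling gave 13 sites denser and 332 less dense, and with it the sites of Klf2, Serbp1 and Lars2 and that of Tubb5 at 35835424 turned to -0.23, -0.20, -0.32 and -0.27. With each position counted once, 41 sites were denser and edgeR called 0 less dense, with 173 at an unadjusted p under 0.05, and DESeq2 on the counts called 1762 and 35. Without replicates 1, 2 and 3 there were 100, 156 and 55 sites denser and 7, 18 and 10 less dense. On the A and the next base alone, the sites of Klf2 and Lars2 turned below 0.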

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

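The ratios in this part had no test and were not among the planned comparisons. They use the base before the A, which was chosen after the data were seen. Positions outside mature mRNAs were not used in the comparisons of genes. In introns, crosslink positions 1 base before a DRACH A were 2.01 ± 0.103 times as frequent as positions moved by 30 nt (SD, n = 3), a signal outside the positions compared. Antisense to genes, the same ratio was 2.07 ± 0.272, again outside the positions compared. Between genes it was 2.14 ± 0.0559. Each ratio was above 1 in 3 of 3 libraries, and the cause was not tested.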

How the results depend on the processing

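Chosen after seeing the data were the near-stop comparisons with the rest of the CDS, with positions 100 nt or more from every junction and with genes that share no exonic base, the base before the A for genes and sites, HCARD windows outside DRACH windows, and the middle of long exons against the first 100 nt after a junction. Unless a reason is given below, the cause was not tested.

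DESeq2 called 2676 genes near the stop codon, of which 2675 were among the 3046 edgeR calls in the same direction, but with 207 lower. It called 11 genes lower at DRACH, 23 lower far from junctions and 1762 sites higher.

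TMM scaling centres the ratios on the typical feature by construction. Its counts of higher and lower features were 1218 and 1319 near the stop codon, 101 and 117 at DRACH, 13 and 332 for sites, 58 and 305 at the 5' end and 247 and 281 for junctions. The median log2 ratio was -0.076 near the stop codon and -0.013 at DRACH. Of the calls in the same direction, 1569 of 3046 remained near the stop codon and 132 of 2391 at DRACH. Near the stop codon, Klf5 turned to -0.024, Hnrnpa2b1 to -0.38, Arid1a to -0.23, Rpl4 to -0.043, Rps3 to -0.11, Atp5a1 to -0.97 and Psmd7 to -0.36. At DRACH, Sox2 turned to -0.20, Lamc1 to -0.39, Rpl4 to -0.15, Rps3 to -0.25, Hk2 to -0.32, Zfp292 to -0.27 and Zfp106 to -0.017. Sites turned to -0.23 in Klf2, -0.20 in Serbp1, -0.27 in Tubb5 and -0.32 in Lars2.

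A count minimum 3 times as high tested fewer features by construction. It gave 1258 genes higher and 204 lower near the stop codon, 1528 higher at DRACH, 33 higher and 45 lower at the 5' end, and 568 higher and 18 lower for junctions. Sites lower rose from 27 to 50, and the cause of that rise was not tested. Without a count minimum, 135 sites were higher and 73 genes were lower at the 5' end.

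The replicate block pairs the classes of 1 library. Without the block, 1140 sites were higher and 41 lower, and the other counts stayed within 1.5 times.

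With each position counted once, 14 genes were lower at DRACH, 41 sites were higher and edgeR called 0 sites lower (173 at an unadjusted p under 0.05, and 35 by DESeq2 on the counts). Hist1h3b turned to 0.067, Hist1h3c to 0.75 and Hist1h4a to 0.40 at DRACH, and the fold at GGACT was 3.78. Shares were 37.6% for CDS, 22.8% for 3' UTRs, 4.64% for noncoding RNA exons, 1.68% for other exons of coding genes, 16.4% for introns and 8.05% for intergenic positions. Without the mitochondrial genome, they were 34.6% for CDS, 21.6% for 3' UTRs, 5.48% for 5' UTRs, 8.59% for noncoding RNA exons, 1.504% for other exons of coding genes, 15.1% for introns, 4.06% for antisense and 9.005% for intergenic positions. This setting takes the mitochondrial RNAs out of both the noncoding exons and the total. The share of positions common to a pair of libraries was 28.8% within 5 nt, a wider match by construction.

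Other windows turned named genes near the stop codon: Spry2 to 0.13 with 100 nt and 0.15 with 400 nt on either side, and Trim71 to -0.89, Arid1a to -0.37, Rps3 to -0.53, Atp5a1 to -0.85 and Pkm to 0.013 with 400 nt of 3' UTR. Against the rest of the CDS, Rps3 turned to -0.17 and Hist1h3c to 3.21, and among positions 100 nt or more from every junction Pkm turned to 0.37. At DRACH, Hist1h4a turned to 1.52 with 5 nt and to 2.56 against HCARD windows, which gave 993 genes higher and 10 lower of 1729 tested. The A and the next base leave out the peak of the profile: they gave 32 genes higher and 4 lower, 9 sites higher and 2 lower, and turned Lamc1 to -0.52, Rps3 to -0.60, Hk2 to -0.47 and the sites in Klf2 and Lars2 to -0.063 and -2.38. On the base before the A alone, 1 gene and 2 sites were lower, and the Ftl1 site turned to -5.42. With a flank of 25 nt, 257 of 9763 tested sites were higher. Over the first 20 nt, 66 genes were higher and 60 lower at the 5' end, and Hnrnpc turned to -3.52 and Ddx5 to -7.28. For junctions, DRACH windows alone gave 297 genes higher and 1 lower of 359 tested, and the middle of long exons gave 267 and 23 of 1215. With 200 nt Nexmif turned to -1.32 and Ptrh2 to -1.24.

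Leaving out each library in turn gave 1732 to 2033 genes higher and 118 to 179 lower near the stop codon, 0 to 1092 and 0 to 9 at DRACH, 55 to 156 and 7 to 18 for sites, 0 to 15 and 0 to 2 at the 5' end, and 920 to 1034 and 10 to 20 for junctions. The counts of 0 came from edgeR, without replicate 2 at DRACH (2007 higher and 22 lower at an unadjusted p under 0.05) and without replicates 1 or 3 at the 5' end (84 and 48, and 93 and 58). Fewer libraries leave fewer degrees of freedom, and at DRACH the prior degrees of freedom went from 212.7 to 2.77 without replicate 2.

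Lists matched on 3' UTR length had adjusted permutation p-values of 0.0745 for ribosomal proteins at DRACH, 0.0945 for glycolysis at DRACH, 0.0945 for proteasome subunits near the stop codon and 0.0468 for C2H2 zinc finger genes near the stop codon. On simulated data, 0% of sites changed 4-fold were recovered, against 44% of genes at the 5' end and 74% of genes near the stop codon. Depth was not varied.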

Other observations

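Among the tests below, the comparison with the rest of the CDS, that of positions 100 nt or more from every junction and that of the middle of long exons were chosen after the data were seen, and so was the reading of the test of start sites. Genes with the most DRACH sites denser than their flanks were Hcfc1, a host cell factor that binds chromatin, with 6, and Eef2, Larp1 and Tubb5 with 5 each. Fat1, Hsp90ab1, Mga, Peg10, Pprc1, Rif1, Slc2a3 and Srrm2 had 4 each. Of 268 tested sites in naive pluripotency genes, 7 were denser, in 4 genes. Klf4 had 3 of them, with the highest at a GAACT in the CDS (chromosome 4, 55528239, GRCm38, log2 ratio 3.66, edgeR adjusted p = 6.88e-05). Zfp42 had 1 at 3.34, with 13 of 18 cDNAs on the base before the A, and Nanog 1 at 2.25, with 0 of 12 there. Core pluripotency genes had 13 of 327 sites denser, among them 4 in Rif1, 3 in Trim71, each at GGACT, and 2 in Sox2 (3.21 and 2.36). Among m6A writers, erasers and readers, 4 of 245 sites were denser, in the demethylase gene Alkbh5 (4.78), the cap methyltransferase gene Pcif1 (3.79), Rbm15b (3.37, a gene that shares exonic bases with another) and Igf2bp1 (2.95). Immediate early and signalling feedback genes had 3 of 116, in Nodal (4.44), Mycn (3.71) and Spry2 (2.21). These genes were chosen after their values were seen.

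No difference between lists was tested. In the other lists with tested sites, the counts of denser sites were 11 of 323 tested sites in chromatin regulators, 5 of 169 in ribosomal proteins, 5 of 91 in histones, 2 of 106 in the respiratory chain, 2 of 60 in proteasome subunits, 1 of 88 in glycolysis, 1 of 110 in epithelial polarity and lumen genes, 7 of 741 in C2H2 zinc finger genes and 0 of 17 in formative and primed genes. At the METTL16-type sequence TACAGAGAA, density over 913 sites was 1.61 ± 0.0913 times the mRNA mean (SD, n = 3), and at TACAGAAAA, over 774 sites, 1.43 ± 0.159 times. A few sites carried much of this: of 44, 44 and 52 cDNAs at TACAGAGAA in replicates 1, 2 and 3, the Sox2 site alone held 12, 13 and 7, and the Mat2a site with the most had 2, 4 and 2.

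Density near the stop codon was higher in 2695 of 5526 tested genes, lower in 351 and not called in 2480. Distance from exon junctions would leave little of this ratio at positions 100 nt or more from every junction, but the median log2 ratio there was 1.09 over 3933 genes. Transcript ends that are annotated but not used would leave little of it against the rest of the CDS, where the median was 0.96 over 4014 genes. Each test left the other explanation in place. Neither was therefore excluded as part of the cause, and junction distance and unused ends acting together were not tested. Uneven coverage of RNA or fragments along mRNAs stays open, since DRACH windows exceeded positions 20 nt or more from every DRACH A by 0.35 on the log2 scale (1.14 against 0.79 on 920 shared genes), between the bounds of 0.25 and 0.5 set for the test. No biological explanation was tested, since the libraries form 1 group.

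Density in coding sequence was lower near exon-exon junctions. Loss of reads that cross a junction would spare the first 100 nt after it, but the middle of long exons was denser than these by a median log2 ratio of 1.25 over 1215 genes, which argues against it as the whole cause. Uneven coverage that ignores the motif would give DRACH windows and distant positions the same ratio, but these differed by 1.02 (2.47 against 1.46 on 302 shared genes). The ratio at distant positions may still be partly due to coverage, and no biological explanation was tested.

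At the 5' end, genes went both ways. Methylated adenosine beside the cap stays open, since the annotated first base was A in 24.6% of genes with higher density and 20.2% of those with lower density (odds ratio 1.29, 95% interval 0.677 to 2.47, two-sided Fisher's exact p = 0.446). Annotated starts that differ from those used stay open too. Genes with cDNAs in the 50 nt upstream of the annotated start were 0.264 times as frequent among genes lower (11.6%) as among genes higher (44.1%), which the prediction had set against this explanation. That bound was wrong, since a start downstream of the annotated one would leave both stretches empty, and the genes lower were picked for few cDNAs in the first 50 nt, so the test decides nothing.

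The 6 sets of counts (2 classes in each of 3 libraries) can be split in 10 ways, too few for a share under 0.05. In each comparison, 1 of the 10 splits, the real one, gave as many calls. The real splits gave 3046 calls near the stop codon, 2391 at DRACH, 471 for sites, 247 at the 5' end and 1336 for junctions. The highest of the other splits by edgeR was 0 in each, with at most 24, 75, 725, 6 and 24 features at an unadjusted p under 0.05. Each other split has both classes of positions on either side, so the difference between classes adds to the spread within a side. Few calls were therefore likely in advance, and the splits cannot tell how many calls arise by chance.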
